A study of Mus musculus with 48 samples.

How the data were processed

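The series holds 48 samples from limbs of C57BL/6 mice at postnatal day 3, of which 36 have a processed file that was used: 12 RNA sequencing libraries and 24 chromatin immunoprecipitation (ChIP) libraries. The 12 input libraries of the ChIP experiment were not used here. Cells had been sorted, per the labels, as skeletal stem cells (SSC), pre-bone, cartilage and stromal progenitors (pBCSP) and bone, cartilage and stromal progenitors (BCSP). The donors carried floxed Ptip alleles, without a Cre transgene (WT) or with Cre under Col2a1 control (KO). Each of the 6 combinations of population and genotype had 2 RNA libraries, 2 H3K27ac libraries, 1 H3K4me1 library and 1 H3K4me3 library. Nothing in the labels says that replicates came from separate animals, so a p-value measures only the spread between these samples, which may be technical. For WT, reads of the X-linked RNA Xist argue against replicates from the same animals, as given under Other observations.

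RNA was selected by its poly(A) tail, per the labels, and whether the libraries kept strand is not given in the sources used here. The RNA files hold whole-number read counts per gene, not normalised, as deposited by the authors for each library. The ChIP files are peak lists, 1 per library, called on MNase-digested chromatin per the labels. For each peak the authors deposited a fold enrichment, a -log10 p, a -log10 q and a score. These were used to describe, rank or filter peaks, and were not tested between lists. The H3K4me1, H3K4me3 and the first set of H3K27ac lists have the layout of broad peaks and the second set of H3K27ac lists that of narrow peaks, so ratios and overlaps between genotypes were taken within a set. The submitters' processing notes name Trim Galore 0.6.6, Bowtie2 2.3.5.1, featureCounts 2.0.1, SAMtools 1.9 and MACS2 2.2.6, and the mouse build GRCm38. Their settings, the gene annotation, the counting of reads shared between genes the cutoffs of the peak caller, and whether WT and KO peaks were called in the same run are not given in the sources used here. Reads shared with a near-identical copy may have been split or dropped in the counts of the globin genes and of glycolysis enzymes that have processed pseudogenes, and these values are uncertain to that extent. Antisense and overlapping genes cannot be told from their partners where strand was not used.

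The 12 RNA libraries held 15495915 to 22670899 counts over 55487 listed genes, of which 55141 IDs were paired with a symbol. Libraries were scaled by the trimmed mean of M values (TMM), genes were kept by filterByExpr with its defaults, which left 17494, and 1 model with a mean per group was fitted to all 12 libraries with the quasi-likelihood test of edgeR 4.0.16 in R 4.3.3. The fit had 6 residual degrees of freedom, 3.38 prior degrees of freedom and a biological coefficient of variation of 0.605. P-values were adjusted by Benjamini-Hochberg and 0.05 was the threshold. KO was compared with WT in each population and on average over the 3 populations, the KO effects were compared between populations by an F test, and WT pBCSP was compared with WT SSC and WT BCSP with WT pBCSP. Fold changes are given as log2 ± SE, with 2 libraries per group, or 6 per genotype for the average effect. Counts scaled to a library size of 1e6 (CPM) use the TMM library sizes, except those of Xist and Ddx3y, which use total counts. A count of 0 was taken to allow up to 3 counts, which is 0.133 to 0.208 CPM over the libraries and covers counting error only. On counts simulated from the real means with 200 changed genes, the average comparison recovered 4% of 2-fold, 36% of 4-fold, 62% of 8-fold and 76% of 16-fold changes, with 9 false calls among 98. The SSC comparison recovered 0%, 2%, 20% and 32%, with 0 false calls among 27. Simulated libraries were independent, with 1 mean over all libraries before the changes and 1 spread for both genotypes. In the data the median difference between replicates was 1.30 log2 in SSC KO against 0.44 in SSC WT. Same-numbered libraries of a genotype also had correlated deviations. These rates may therefore not hold for the real libraries.

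The 31 gene lists were written from general knowledge. They cover subunits of the PTIP and H3K4 methyltransferase complexes; glycolysis, oxidative phosphorylation, hypoxia, S phase, G2 and M phase, p53, DNA double-strand breaks, Hox genes, and Wnt, BMP and TGF-beta, hedgehog, Notch and interferon signalling; chondrocytes, hypertrophic chondrocytes, osteoblasts, skeletal progenitors and the surface markers of the sorting scheme. Further lists are leukocyte, erythroid, endothelial, skeletal muscle, osteoclast, tendon, pericyte, adipocyte and Schwann cell genes, immediate early genes, mitochondrially encoded transcripts and sex-linked genes. Of 508 listed genes 507 were found in the count files. Each list was tested with camera (limma 3.58.1), which asks whether its genes moved relative to all other genes, with a preset correlation between genes of 0.01 and adjustment over the 31 lists of a comparison. It was repeated with a correlation estimated from the libraries and with fry, which asks whether the list moved at all on balance. The text uses the directional p of fry; its mixed p, which lets members of a list move either way, passed 20 lists on average, mitochondrially encoded transcripts in pBCSP and surface markers between WT BCSP and pBCSP (adjusted p = 0.0431), and 0 lists in SSC and BCSP. With the estimated correlation no list passed in any of the comparisons; fry passed 2 lists on average over the populations and 0 in each other comparison. Where members had a group at 0, setting them to their bound moved the median of the leukocyte list in pBCSP from -3.27 to -1.48, of the osteoblast list in pBCSP from -0.79 to -0.36 and of the adipocyte list from -2.06 to -0.69 in SSC and from -2.29 to -1.86 on average; among the other lists with a call the leukocyte list in BCSP moved from -1.35 to -1.24 and the rest by at most 0.03.

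The genes named in the text follow a rule with 5 parts. (1) Paxip1 and the surface markers of the sorting scheme are given in every comparison. (2) In each comparison of KO with WT, up to 8 higher and 8 lower genes are named by size among those past the threshold with a mean of at least 5 CPM and both KO libraries on the same side of both WT libraries, leaving out predicted genes, pseudogenes and the erythroid and leukocyte lists. (3) For each list, up to 2 higher and 2 lower members with the smallest adjusted p are named, or the member with the highest CPM where none passed, and Pgk1, Ldha, Sox9, Col2a1, Runx2 and Pdgfra are given whether or not they pass. (4) For the average effect and the WT comparisons, up to 5 higher and 5 lower genes by (2) and list members by (3) are named. (5) At promoters the genes of (1) to (3) are used. Genes named beyond it are said to be so where they appear.

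Peak lists were compared within a population by the number of peaks, the covered length and the share of peaks with at least 1 base in a peak of the other genotype. The H3K27ac peak numbers were tested by exact two-sided permutation of the libraries of a population, which exchanges broad and narrow lists, and, over the 3 populations, also within sets. Gene positions came from an NCBI RefSeq table of GRCm38.p6, which gives the start and end of a gene and not its strand. The promoter of a protein-coding gene was taken as the 1 kb to either side of the end with more H3K4me3; of 21883 genes placed, 13200 had such an end, 1440 used both ends and 7243 had none. Genes with a promoter peak in WT but not KO, or in KO but not WT, were tested as sets with camera on the RNA, where at least 10 were measured. Peaks and tables were handled in Python 3.11.15 with pandas 2.3.3 and numpy 2.4.6, and plots were drawn with matplotlib 3.10.9.

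The tests, the lists, the rule for named genes and these alternatives were set before the data were examined: scaling by size factors, DESeq2 1.42.0, no filter on low counts, the replicate number as a block, a log2 fold change of at least 1, each library left out in turn, only the 4 libraries compared, a stricter peak threshold (-log10 q of at least 5), an overlap of 50% of the peak, equal numbers of top peaks, and a promoter window of 2.5 kb. Added after the data were seen were fits with 1 library per KO group, fits of pBCSP and BCSP alone, library quality weights in limma, counts summed over populations, a correlation between libraries that share a genotype and replicate number, permutation within H3K27ac set, exact permutation of H3K4me1 and H3K4me3 over the populations, and promoter sets taken from either gene end. The gene table carries no sequence, so no positions within genes were analysed here.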

Results

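RNA and 3 histone marks were profiled in cells sorted from mouse limbs at postnatal day 3 as SSC, pBCSP and BCSP, 3 populations of the early skeletal lineage. The comparison the design implies is between cells of mice with floxed Ptip alleles alone (WT) and of mice that also carried Cre under control of Col2a1, the gene of the main cartilage collagen (KO). Ptip, now named Paxip1, encodes an adaptor of H3K4 methyltransferase complexes. Each group had 2 RNA libraries, and libraries held 15495915 to 22670899 counts. Between 20965 and 23831 genes had a read in 11 of the libraries, whereas SSC KO replicate 2 had a read in 13987 genes from 18079436 counts. The median difference between replicates was 0.44 log2 in SSC WT, 0.40 in pBCSP WT and 0.35 in BCSP WT, and 1.30, 0.67 and 0.63 in the KO groups. H3K27ac, a mark of active promoters and enhancers, had 2 libraries per group, and H3K4me1 (enhancers) and H3K4me3 (promoters) had 1 library per group.

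Paxip1 (ENSMUSG00000002221; GRCm38 chromosome 5, 27740080 to 27791672) had fewer counts in every KO library than in any WT library. WT levels were 13.7 and 11.8 CPM in SSC, 14.6 and 7.56 CPM in pBCSP, and 13.2 and 7.25 CPM in BCSP. KO levels were 0.347 and 0 CPM in SSC, 0.568 and 0.0904 CPM in pBCSP, and 3.48 and 0.791 CPM in BCSP; the 0 allows up to 0.166 CPM. On average over the populations Paxip1 fell by 4.52 ± 0.76 log2 (adjusted p = 0.0396, 6 of 6 KO libraries below the WT mean). By population the log2 differences were -6.22 ± 1.45 in SSC, -5.09 ± 1.35 in pBCSP and -2.25 ± 1.16 in BCSP. These did not pass in edgeR (adjusted p = 0.524, 0.74 and 0.832), while DESeq2 gave adjusted p = 0.000478, 0.00201 and 0.347. Counts run over the whole gene and the labels do not say which exons are floxed. The average call was lost when any of 9 libraries was left out: SSC WT replicate 1 (adjusted p = 0.0844) or 2 (0.168), pBCSP WT replicate 1 (0.119) or 2 (0.168), BCSP WT replicate 1 (0.148) or 2 (0.194), pBCSP KO replicate 1 (0.0714) or 2 (0.145), and BCSP KO replicate 2 (0.143).

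Genes of glycolysis rose in KO cells on average over the 3 populations. Of the 21 measured, 12 rose past the threshold over all genes and 17 adjusted over the list alone, with a list median of 1.27 log2. Pgk1, which makes ATP in the lower part of the pathway, rose by 1.63 ± 0.23 log2 (3.10-fold, adjusted p = 0.0266). Ldha, which turns pyruvate into lactate, rose by 1.54 ± 0.23 (adjusted p = 0.0312). Gpi1, the isomerase that follows glucose phosphorylation, rose by 1.23 ± 0.13 (0.0244), and Pkm, which makes pyruvate, by 1.36 ± 0.17 (0.0261). All 4 were above the WT mean in 6 of 6 KO libraries. Among genes named after their values were seen, Tpi1 rose by 2.17 ± 0.30 (0.0266), Eno1 by 1.72 ± 0.23 (0.0266) and the lactate exporter Slc16a3 by 2.36 ± 0.37 (0.0346). The glucose transporter Slc2a1 (0.67 ± 0.21, adjusted p = 0.135) and hexokinase Hk2 (0.10 ± 0.18, 0.794) did not pass. By camera the list was higher (adjusted p = 1.95e-23; adjusted p = 0.22 with an estimated correlation), and fry gave an adjusted p of 0.0154. These single-gene calls were lost without any 1 of the 6 WT libraries, without replicate 2 of pBCSP KO or BCSP KO, and with counts summed over populations, where 0 genes passed in edgeR (1505 to 3016 at an unadjusted p under 0.05). The list median was positive in each KO library, from 0.95 in SSC KO replicate 1 to 1.56 in SSC KO replicate 2.

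**Figure D1:**
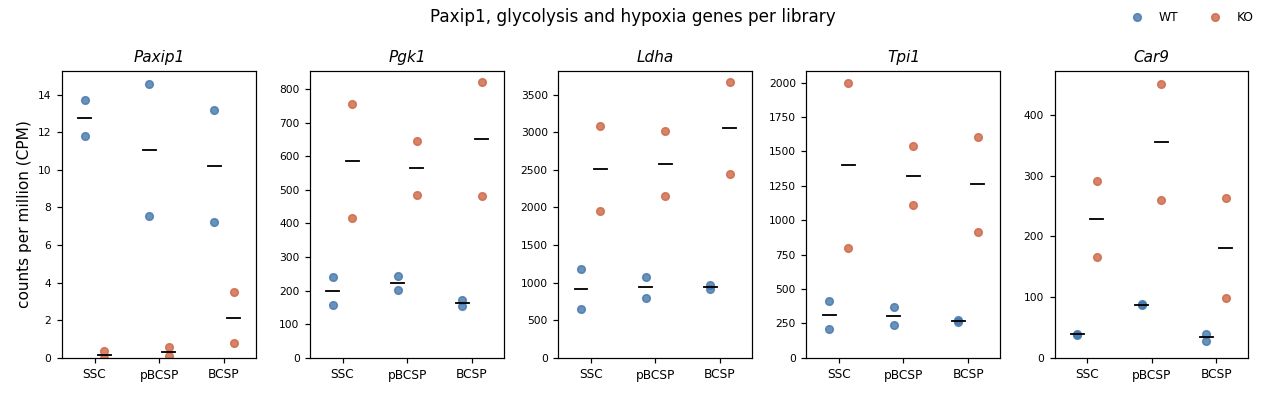
CPM of Paxip1, 3 glycolysis genes and Car9 in each of the 12 RNA libraries (points; bars are the mean of 2 libraries), by population and genotype. Pgk1, Ldha, Tpi1 and Car9 lie higher in every KO library than in any WT library of the same population, and Paxip1 lies lower.

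The hypoxia list also rose (median 1.15 log2, adjusted p = 3.24e-05 by camera; adjusted p = 0.569 with an estimated correlation). Only 3 of its 15 genes passed, and 8 adjusted over the list alone. Car9, a carbonic anhydrase of the cell surface, rose by 2.34 ± 0.29 log2 (adjusted p = 0.0244), and the collagen prolyl hydroxylase subunits P4ha1 and P4ha2 rose by 1.57 ± 0.14 (0.0206) and 1.22 ± 0.23 (0.049). P4ha2 and Vegfa were named after their values were seen. Vegfa, the vascular growth factor, was 0.49 ± 0.38 (0.501), and 5 members had a negative difference. In the KO libraries the list median was 0.11, 0.34 and 0.41 in the first replicates and 1.54, 1.02 and 1.37 in the second.

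Chondrocyte genes rose on average as well: 14 of 24 measured passed, and 18 adjusted over the list alone, with a median of 1.15 log2 and 23 of 24 differences above 0. Matn1, a cartilage matrix protein, rose by 3.00 ± 0.33 log2 (8.03-fold, adjusted p = 0.0244), and Ucma, a matrix protein of growth plate cartilage, by 1.96 ± 0.26 (0.0266). Col2a1, the main cartilage collagen gene, was -0.07 ± 0.24 (0.9), and Sox9, the transcription factor of the chondrocyte lineage, 0.51 ± 0.22 (0.24). Named after their values were seen, Epyc rose by 2.87 ± 0.45 (0.0346), Col9a1 by 1.16 ± 0.21 (0.0484) and the transcription factor gene Sox5 by 1.07 ± 0.21 (0.0495). The list was higher by camera (adjusted p = 4.35e-26; adjusted p = 0.22 with an estimated correlation) and by fry (0.0154), with medians of 0.76 to 2.03 in the 6 KO libraries. The calls of single chondrocyte and hypoxia genes, and of those named next, were lost in at least the same refits and with pBCSP and BCSP alone. Some were lost in more: over 24 alternatives Ppp1r3b kept its call in 8 and Cyp1b1 and Frzb in 9, against 14 for Pgk1. Genes of hypertrophic chondrocytes did not pass as a list (median 0.31, adjusted p = 0.226), nor did the osteoblast list (-1.12, 0.121), and Runx2, which drives osteoblast formation, was 0.69 ± 0.27 (0.208).

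**Figure D2:**
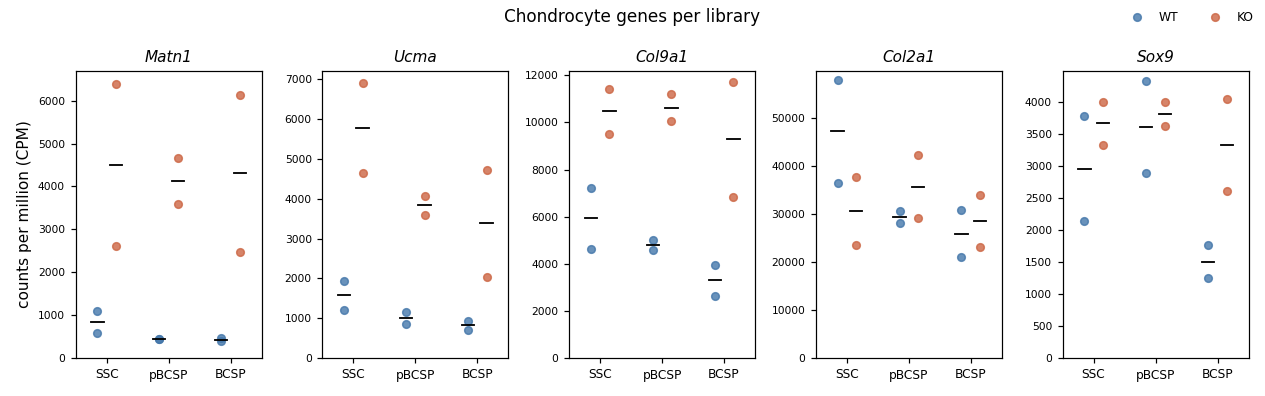
CPM of 5 chondrocyte genes in each of the 12 RNA libraries (points; bars are the mean of 2 libraries), by population and genotype. Matn1, Ucma and Col9a1 lie above the WT libraries in every KO library, whereas Col2a1 and Sox9, which did not pass on average, overlap between genotypes in some populations.

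The other genes that rose most on average by the naming rule were Ppp1r3b, a subunit that directs a phosphatase to glycogen (4.88 ± 0.94 log2, adjusted p = 0.0494), Sfrp5, a secreted Wnt inhibitor (3.87 ± 0.54, 0.0266), Necab3 (3.85 ± 0.59, 0.0312), Apela, a ligand of the apelin receptor (3.80 ± 0.66, 0.0421), and Kctd4 (3.61 ± 0.66, 0.0472). Besides Paxip1, those that fell most were Cyp1b1, a cytochrome P450 (-5.06 ± 0.94, 0.0483), Rgs4, a regulator of G protein signalling (-3.91 ± 0.74, 0.049), Fkbp5, a co-chaperone of the glucocorticoid receptor (-2.40 ± 0.41, 0.0418), and Agfg2 (-1.86 ± 0.24, 0.0261). Each of these lay on 1 side of the WT mean in 6 of 6 KO libraries. The PTIP complex list did not pass (median -0.32, adjusted p = 0.181), and Paxip1 alone of its 14 measured genes passed, 1 adjusted over the list alone. Frzb, a secreted Wnt inhibitor, rose by 1.58 ± 0.30 (0.049), Ifi27 of the interferon list by 1.29 ± 0.18 (0.0277) and S100b of the Schwann cell list by 1.84 ± 0.27 (0.0312).

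A further 9 lists were lower on average by camera, although none of their members passed as lower over all genes. For adipocyte genes the median was -2.29 log2 (adjusted p = 0.00216), for erythroid genes -2.77 (0.00216), for endothelial genes -1.66 (0.00714), for skeletal progenitor genes -0.72 (0.00714), for Wnt genes -0.92 (0.00847), for G2 and M phase -0.46 (0.0117), for Notch targets -1.12 (0.0117), for tendon genes -0.81 (0.022) and for BMP and TGF-beta genes -0.49 (0.022). Adjusted over the list alone, 4 erythroid, 2 BMP and TGF-beta and 1 Wnt gene passed as lower and 0 in the others, and Frzb passed as higher. With an estimated correlation the adjusted p was 0.569 for adipocyte, erythroid, endothelial and tendon genes, 0.613 for G2 and M phase and 0.594 for the other 4. Pdgfra, a receptor of stromal progenitors, was -0.94 ± 0.24 (0.0885), the haemoglobin gene Hba-a1 -2.77 ± 0.63 (0.0724) and Cdc20, which acts at the end of mitosis, -1.03 ± 0.33 (0.144). Several of these medians differed between the KO replicates: for adipocyte genes they were -0.64, -1.18 and -1.29 in the first replicates of SSC, pBCSP and BCSP and -4.55, -4.45 and -3.41 in the second. For endothelial genes they were 0.32, -1.06 and -1.9 against -1.91, -3.16 and -2.42. For Notch targets they were -0.58, 0.16 and -0.54 against -3.95, -1.08 and -2.66, and for G2 and M phase -0.47, -0.23 and 0.14 against -2.29, -0.69 and 0.15. Wnt medians were -0.28, -0.68 and -0.68 against -2.53, -1.29 and -1.88, and tendon medians -0.19, -0.53 and -0.51 against -0.74, -1.76 and -2.44. Progenitor medians were -0.24, -0.45 and -0.72 against -0.75, -1.18 and -1.58. BMP and TGF-beta medians were -0.45, -0.19 and 0.13 against -1.73, -1.27 and -0.40. Erythroid medians were -1.09, -2.03 and -1.40 against -2.13, -2.19 and -2.40. Immediate early genes, which dissociation of tissue can induce, did not pass (median -0.55, adjusted p = 0.121) but had medians of 0.19, 0.42 and 0.04 in the first and -2.54, -3.80 and -1.63 in the second KO replicates. Without SSC KO replicate 1 the calls of the progenitor (adjusted p = 0.0864), BMP and TGF-beta (0.0542), erythroid (0.0542) and tendon lists (0.0952) were lost, and without pBCSP KO replicate 2 that of the BMP and TGF-beta list (0.0796).

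Lists that passed in neither direction on average, with their median and adjusted p, were oxidative phosphorylation (0.11, 0.0583), surface markers (-0.71, 0.121), S phase (0.12, 0.409), p53 targets (-0.26, 0.307), double-strand break response (0.18, 0.416), Hox genes (-0.26, 0.692) and hedgehog targets (-0.80, 0.228). The same held for interferon (-0.06, 0.652), mitochondrially encoded (0.00, 0.705), leukocyte (-1.33, 0.0579), skeletal muscle (-0.62, 0.623), osteoclast (-0.20, 0.17), pericyte (-1.45, 0.0715), Schwann cell (-1.96, 0.0603) and sex-linked genes (0.17, 0.382). Adjusted over the list alone, 1 hypertrophic, 1 muscle, 1 pericyte, 1 interferon and 1 Schwann cell gene passed as higher, and 2 hedgehog, 1 osteoclast and 1 PTIP complex gene as lower. For the Hox and interferon lists the mean was 0.02 and 0.16, of the opposite sign to the median, and for the sex-linked list it was -1.16. Of the surface markers, the integrin gene Itgav was -0.71 ± 0.32 log2 (adjusted p = 0.253), Cd200 -0.18 ± 0.23 (0.687), Eng, which encodes CD105, -0.29 ± 0.15 (0.303), Enpep -1.38 ± 1.08 (0.507) and Tek -1.05 ± 1.27 (0.677).

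**Figure D3:**
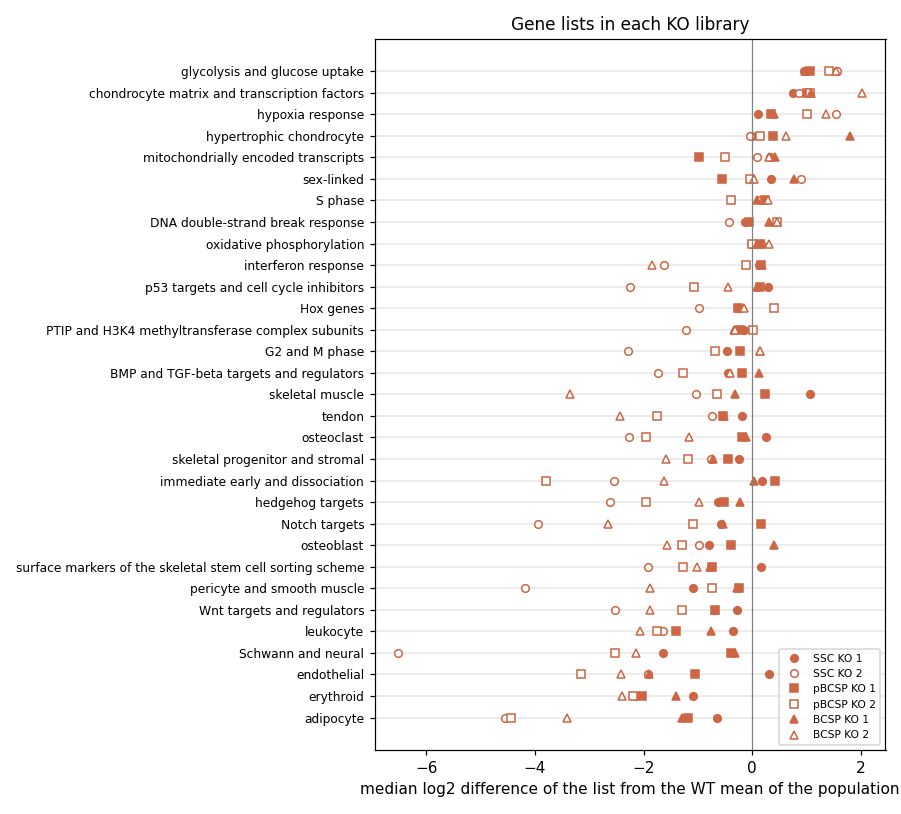
Median log2 difference of each of the 31 gene lists from the WT mean of the same population, in each of the 6 KO libraries (symbols by population, filled for replicate 1 and open for replicate 2). The glycolysis and chondrocyte lists lie above 0 in all 6 libraries; for the immediate early and adipocyte lists, replicate 2 of each population lies far below replicate 1.

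In all, 205 of 17494 genes passed on average in edgeR, 169 higher and 36 lower, with 3431 at an unadjusted p under 0.05; DESeq2 gave 1735 (1077 higher and 658 lower), among them all 205. The count depends on single libraries. It was 0 without either WT replicate of SSC, pBCSP or BCSP and without replicate 2 of pBCSP KO or BCSP KO, 29 without pBCSP KO replicate 1, 349 without BCSP KO replicate 1 and 6147 without SSC KO replicate 1. In those edgeR fits with 0 genes, 2242 to 3016 had an unadjusted p under 0.05. It was also 0 when only pBCSP and BCSP were fitted (3684 at an unadjusted p under 0.05) and 0 when counts were summed over populations into 2 samples per genotype (1505). Libraries of different populations may share animals: with a correlation between libraries of the same genotype and replicate number, estimated at 0.329, limma passed 44 genes, all among the 205, against 462 without it.

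In SSC, glycolysis genes were higher in KO as a list (median 1.29 log2, 18 of 21 above 0, 14 adjusted over the list alone, adjusted p = 1.96e-13), as were hypoxia (1.14, 4 of 15, 8.21e-05), chondrocyte (0.71, 2 of 24, 2.47e-09) and oxidative phosphorylation genes (0.12, 0 of 42, 0.0449). Genes of G2 and M phase were lower (-1.10, all 23 below 0, 1.22e-05), and so were Notch targets (-1.69), erythroid (-2.06), pericyte (-2.07) and Schwann cell genes (-2.64; adjusted p = 0.0449 for each of the 4 lists). No gene of these 5 passed adjusted over the list alone. Against the WT mean, SSC KO replicates 1 and 2 had medians of -0.47 and -2.29 for G2 and M phase, -0.58 and -3.95 for Notch, -1.09 and -4.19 for pericyte and -1.64 and -6.52 for Schwann cell genes, and 0.11 and 1.54 for hypoxia genes. All 9 lists had adjusted p = 0.783 with an estimated correlation, and fry passed none. Pgk1 was 1.57 ± 0.39 log2 and Ldha 1.46 ± 0.40 (adjusted p = 0.524 for both). Others with both KO libraries above the WT mean were Ifi27 (1.82 ± 0.32, 0.524), the fast muscle troponin gene Tnni2 (3.39 ± 0.77, 0.524) and the leukocyte gene Laptm5 (4.10 ± 1.33, 0.524). The muscle and leukocyte lists did not pass in SSC (medians 0.39 and -0.10). Their medians in SSC KO replicates 1 and 2 were 1.06 and -1.04 for muscle and -0.36 and -1.65 for leukocyte genes. Sox9 (0.31 ± 0.38), Col2a1 (-0.62 ± 0.41), Runx2 (-0.15 ± 0.47) and Pdgfra (-0.23 ± 0.41) did not pass, nor did Cdc20 (-1.56 ± 0.58), Cd200 (0.11 ± 0.40), Eng (0.11 ± 0.25) or Itgav (-0.62 ± 0.55). The SSC KO libraries differed most from each other, and the median over all 17494 genes was -0.22.

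In edgeR 0 genes passed in SSC (1643 at an unadjusted p under 0.05, smallest adjusted p 0.524), 174 in DESeq2 (134 higher and 40 lower) and 5908 in edgeR without SSC KO replicate 1, where replicate 2, with a read in 13987 genes, is the sole SSC KO library. Glycolysis, chondrocyte and G2 and M phase kept their list call in 15 of 15 refits. Without SSC KO replicate 2 the calls of hypoxia (adjusted p = 0.104), oxidative phosphorylation (0.738), Notch (0.0945), erythroid (0.0945), pericyte (0.104) and Schwann cell genes (0.0945) were lost. Without SSC KO replicate 1 those of Notch (0.1), erythroid (0.342), pericyte (0.0547) and Schwann cell genes (0.132) were lost. Leaving out SSC WT replicate 1 ended that of erythroid genes (0.196), and leaving out SSC WT replicate 2 those of oxidative phosphorylation (0.207), Notch (0.0601) and pericyte genes (0.238). Oxidative phosphorylation was also lost without pBCSP WT replicate 1 (0.0535) or 2 (0.0556), pBCSP KO replicate 2 (0.0562) and BCSP WT replicate 1 (0.0541) or 2 (0.0549). Pericyte genes were lost without pBCSP KO replicate 2 (0.0509).

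In pBCSP, glycolysis genes (median 1.23 log2, 20 of 21 above 0, 13 adjusted over the list alone, adjusted p = 1.34e-16), chondrocyte genes (1.01, 24 of 24 above 0, 10, 5.46e-17) and hypoxia genes (0.79, 2, 0.00158) were higher in KO as lists. The lower lists numbered 13. Mitochondrially encoded transcripts were below 0 in 12 of 12 (median -0.69, 2 adjusted over the list alone, 4.36e-06). The member with the highest CPM was mt-Cytb of the respiratory chain (-1.18 ± 0.28, adjusted p = 0.74). Leukocyte (-3.27, 0.000311), endothelial (-1.85, 0.000123), adipocyte (-2.29, 0.00103) and erythroid genes (-2.78, 0.00541) were lower, the last with 2 adjusted over the list alone. So were osteoblast (-0.79, 0.00417), progenitor (-0.81, 0.00538), Wnt (-1.32, 0.00541), BMP and TGF-beta (-0.63, 0.0062), tendon (-0.87, 0.00741), G2 and M phase (-0.53, 0.011), immediate early (-0.38, 0.0142) and osteoclast genes (-0.62, 0.0455). Of these 8 lists only the Wnt list had genes passing adjusted over the list alone, 1 higher and 1 lower. With an estimated correlation adjusted p was 0.282 for glycolysis, chondrocyte, mitochondrial and leukocyte genes and 0.435 to 0.673 for the others, and fry passed none. Pgk1 was 1.34 ± 0.39 log2 and Ldha 1.46 ± 0.40 (adjusted p = 0.74 for both), S100b 1.80 ± 0.47 (0.74) and Hba-a1 -4.18 ± 1.16 (0.74). Sox9 (0.08 ± 0.38), Col2a1 (0.28 ± 0.41), Runx2 (0.68 ± 0.47), Pdgfra (-0.77 ± 0.41), Cd200 (-0.60 ± 0.40), Eng (-0.08 ± 0.25) and Itgav (-0.99 ± 0.55) did not pass.

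In edgeR 0 genes passed in pBCSP (1096 at an unadjusted p under 0.05, smallest adjusted p 0.51) and 107 in DESeq2 (79 higher and 28 lower). Glycolysis, chondrocyte, mitochondrial, leukocyte and endothelial genes kept their list call in 15 of 15 refits. In pBCSP KO replicates 1 and 2 the medians were 0.42 and -3.80 for immediate early, -1.18 and -4.45 for adipocyte, -1.06 and -3.16 for endothelial and -0.19 and -1.27 for BMP and TGF-beta genes. Without pBCSP KO replicate 2 only 6 lists passed, and the calls of hypoxia (adjusted p = 0.134), osteoblast (0.17), progenitor (0.26), G2 and M phase (0.35), Wnt (0.486), BMP and TGF-beta (0.518), immediate early (0.35), osteoclast (0.949), tendon (0.221) and adipocyte genes (0.0932) were lost. The erythroid call was lost without pBCSP KO replicate 1 (0.113) or pBCSP WT replicate 2 (0.444), the progenitor call without pBCSP WT replicate 2 (0.0841), and the osteoblast (0.0566) and immediate early calls (0.147) without pBCSP WT replicate 1. The osteoclast call, on 4 measured genes, was also lost without either WT replicate of pBCSP (0.062 and 0.336) and without any 1 library of SSC or BCSP (0.127 to 0.153).

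In BCSP, chondrocyte genes were higher in KO in 24 of 24 (median 1.67 log2, 21 adjusted over the list alone, adjusted p = 2.03e-33), followed by glycolysis (1.32, 15, 2.45e-19), hypoxia (0.94, 5, 0.0018), hypertrophic chondrocyte (1.23, 0, 0.0185) and oxidative phosphorylation genes (0.18, 0, 0.044). Progenitor genes were lower (-1.14, 4.64e-05), with Pdgfra at -1.82 ± 0.42 (adjusted p = 0.451 over all genes and the 1 progenitor gene passing adjusted over the list alone), as were endothelial (-2.37, 0.000527), Notch (-1.37, 0.00127), adipocyte (-2.07, 0.0018), erythroid (-2.25, 0.00608) and Wnt genes (-0.73, 0.00867). Surface markers (-0.90, 0.0214), leukocyte (-1.35, 0.0228), tendon (-0.77, 0.0251) and skeletal muscle genes (-1.25, 0.0402) were lower too. Eng of the surface markers and 0 genes of the other 8 lower lists passed adjusted over the list alone. With an estimated correlation adjusted p was 0.224 for chondrocyte and glycolysis genes and 0.474 to 0.68 for the others, and fry passed none. Pgk1 was 2.00 ± 0.39 log2 (adjusted p = 0.447), Eno1 2.13 ± 0.40 (0.447) and Ldha 1.70 ± 0.40 (0.463). Sox9 was 1.15 ± 0.38 (0.676), Runx2 1.54 ± 0.48 (0.643), Col2a1 0.14 ± 0.41 (0.98), Eng -0.90 ± 0.25 (0.583), Cd200 -0.06 ± 0.40 (0.994) and Itgav -0.53 ± 0.55 (0.928).

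In edgeR 0 genes passed in BCSP (1095 at an unadjusted p under 0.05, smallest adjusted p 0.447) and 124 in DESeq2 (95 higher and 29 lower). Glycolysis, hypoxia, chondrocyte, progenitor, Wnt, Notch, endothelial and adipocyte genes kept their list call in 15 of 15 refits. In BCSP KO replicates 1 and 2 the medians were -0.54 and -2.66 for Notch, -0.31 and -3.36 for muscle, -0.51 and -2.44 for tendon and 0.41 and 1.37 for hypoxia genes. The hypertrophic call was lost without BCSP KO replicate 1 (adjusted p = 0.327), BCSP WT replicate 2 (0.139) or SSC KO replicate 1 (0.052). The erythroid call was lost without BCSP WT replicate 2 (0.0834) or SSC KO replicate 1 (0.052), and the leukocyte call without BCSP KO replicate 1 (0.0827) or 2 (0.101) or pBCSP WT replicate 1 (0.0516). The muscle call was lost without BCSP KO replicate 2 (0.938) or BCSP WT replicate 2 (0.122), and the tendon call without BCSP KO replicate 2 (0.136) or BCSP WT replicate 1 (0.08). Surface markers were lost without BCSP WT replicate 1 (0.557), either BCSP KO replicate (0.0547 and 0.556), either replicate of pBCSP KO (0.0952 and 0.097), pBCSP WT replicate 2 (0.103) or any SSC library (0.0904 to 0.11). Oxidative phosphorylation was lost without BCSP WT replicate 1 (0.557), either BCSP KO replicate (0.0606 and 0.279), pBCSP KO replicate 1 (0.0509), either pBCSP WT replicate (0.0641 and 0.0692), either SSC WT replicate (0.0639 and 0.0669) or SSC KO replicate 2 (0.068).

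Whether the KO effect differed between populations was tested directly. In edgeR 0 genes passed, with 240 at an unadjusted p under 0.05, 3 passed in the likelihood ratio test of DESeq2, and 2082 passed in edgeR without SSC KO replicate 1. Across genes, which are not independent replicates, the log2 KO effects had r = 0.36 between SSC and pBCSP, 0.37 between SSC and BCSP and 0.55 between pBCSP and BCSP. Same-numbered libraries of a genotype also had correlated deviations across populations (0.29 to 0.49 in KO and 0.28 to 0.33 in WT), so these r do not measure a shared KO effect alone. Chondrocyte genes were raised less in SSC than in BCSP (difference of the effects -0.84 log2, adjusted p = 0.000177; adjusted p = 0.91 with an estimated correlation). The KO effect on mitochondrially encoded transcripts was lower in pBCSP than in the other populations (by camera, SSC minus pBCSP 1.06, adjusted p = 1.09e-08; pBCSP minus BCSP -1.22, 1.51e-14). Neither passed with an estimated correlation (adjusted p = 0.261 and 0.167), and both passed in the mixed test of fry (0.0277 and 0.0171), as did this list in pBCSP (0.00404).

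The WT libraries show how the sorted populations differ in control mice. Differences in genes of the surface markers used for sorting may be set by the sort itself. In pBCSP compared with SSC, osteoblast genes (median -2.08 log2, 7 adjusted over the list alone, adjusted p = 1.74e-17), hypertrophic chondrocyte genes (-2.67, 4, 4.75e-15), Schwann cell genes (-4.40, 1, 5.34e-15) and chondrocyte genes (-0.48, 0, 4.07e-05) were lower as lists, and Notch targets (-1.0, 0, 0.022) and pericyte genes (-1.02, 0, 0.0229) as well. Endothelial (2.58, 7.42e-13), leukocyte (1.61, 7.59e-07), progenitor (0.88, 1.54e-06), tendon (1.12, 2.79e-05), adipocyte (1.46, 0.00333) and muscle genes (1.31, 0.0386) were higher, with 0 genes adjusted over the list alone. Cd200, a surface marker of the sorting scheme, had 244 CPM in SSC, 26.7 in pBCSP and 104 in BCSP, a difference of -3.19 ± 0.43 log2 between pBCSP and SSC (adjusted p = 0.318 in edgeR and 8.28e-08 in DESeq2). Alpl, an enzyme of mineralising cells, was -4.11 ± 1.30 (1), the lipase gene Lpl 2.19 ± 0.70 (1) and Paxip1 -0.21 log2. With an estimated correlation adjusted p was 0.0669 for osteoblast, hypertrophic, Schwann and leukocyte genes, 0.0677 for endothelial, 0.158 for tendon, 0.255 for progenitor, 0.636 for adipocyte and 0.707 for the other 4 lists, and fry passed none. In edgeR 0 genes passed (330 at an unadjusted p under 0.05), 40 in DESeq2 and 110 when only these 4 libraries were fitted. The chondrocyte call was lost without SSC WT replicate 1 (adjusted p = 0.844), the Notch (0.406), pericyte (0.837) and adipocyte calls (0.115) without SSC WT replicate 2, and the Notch (0.243) and pericyte calls (0.571) without pBCSP WT replicate 1. The muscle call was lost without any 1 of 11 libraries, all but BCSP KO replicate 1 (0.123 to 0.724).

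In WT BCSP compared with pBCSP, osteoblast genes (median 1.39 log2, 3 adjusted over the list alone, adjusted p = 1.73e-10), hypertrophic chondrocyte genes (1.51, 2, 1.04e-08), muscle genes (2.36, 0, 7.94e-07), surface markers (1.04, 2, 4.58e-06), interferon genes (1.42, 0, 6.87e-06), Schwann cell genes (2.06, 1, 0.000978), S phase genes (0.42, 0, 0.00346) and Notch targets (1.43, 0, 0.0105) were higher. Chondrocyte (-0.42, 0, 3.11e-07), glycolysis (-0.23, 1, 0.0241) and leukocyte genes (-0.76, 0, 0.0387) were lower. The differences of the surface markers, Eng and Cd200 among them, may again be set by the sort. Eng was higher by 2.21 ± 0.26 log2 (adjusted p = 0.193 in edgeR and 3.35e-13 in DESeq2), Cd200 was 1.96 ± 0.41 (1 and 0.0185), Sox9 -1.27 ± 0.38 (1) and the Wnt inhibitor Wif1 -1.93 ± 0.52 (1). The adjusted p with an estimated correlation was 0.219 for osteoblast, hypertrophic, surface marker and S phase genes, 0.222 for muscle and interferon, 0.484 for chondrocyte, Schwann and leukocyte, 0.676 for Notch and 0.695 for glycolysis genes, and fry passed none. In edgeR 0 genes passed (458 at an unadjusted p under 0.05), 36 in DESeq2 and 417 when only these 4 libraries were fitted. Glycolysis was lost without pBCSP WT replicate 1 (adjusted p = 0.604), BCSP WT replicate 2 (0.102) and SSC KO replicate 1 (0.0872) or 2 (0.0684). Leukocyte genes were lost without pBCSP WT replicate 1 (0.577) or BCSP WT replicate 1 (0.207), and Schwann cell genes without pBCSP WT replicate 1 (0.0769) or BCSP WT replicate 2 (0.0867). Notch was lost without pBCSP WT replicate 1 (0.0925) and surface markers without BCSP WT replicate 1 (0.0682).

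H3K27ac peaks were more numerous in KO than in WT SSC and BCSP and fewer in KO pBCSP, in both sets of lists. In the first set, SSC had 1828 peaks in WT and 2203 in KO, pBCSP 6879 and 4783, and BCSP 6236 and 7951. In the second set SSC had 137 and 1119, pBCSP 3811 and 1105, and BCSP 785 and 8572. The mean log2 ratio of KO to WT was 1.65 in SSC (exact permutation p = 0.667), -1.16 in pBCSP (0.667) and 1.9 in BCSP (0.333), where 0.333 is the smallest p that 2 against 2 libraries can give. Over the 3 populations it was 0.80 (exact two-sided permutation p = 0.38 over 216 labelings, smallest possible 0.00926; within sets p = 0.375), and for the covered length 0.92 (p = 0.481). The labelings within a population exchange broad and narrow lists, and the mean over populations joins ratios of opposite sign, so these tests do not settle whether the numbers differ within a population. With the stricter threshold the first BCSP set turned, with 434 peaks in WT and 87 in KO. Replicate lists shared few places: of the peaks in a second-set list, 23.8% to 46.5% overlapped the first set of the same genotype and 21.8% to 59.3% that of the other genotype.

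**Figure D4:**
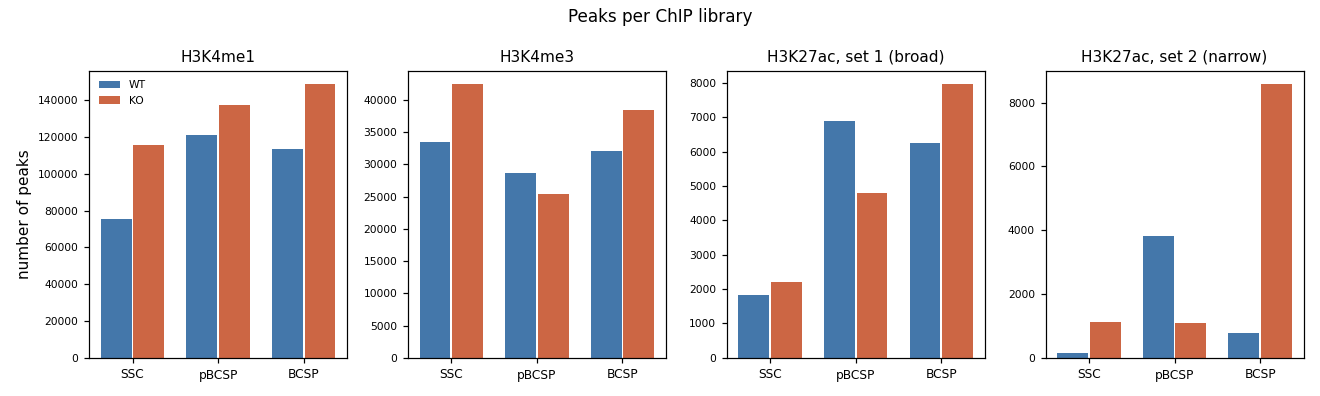
Number of peaks in each of the 24 ChIP libraries, by mark, population and genotype; each bar is 1 library, and the y axes differ between panels. H3K27ac peaks are more numerous in KO in SSC and BCSP and in WT in pBCSP, in both sets, and range from 137 to 8572.

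H3K4me1 covered more of the genome in every KO library than in its WT counterpart, with 1 library per group. Over the 3 populations the mean log2 ratio of covered length was 0.62 ± 0.19 for H3K4me1 and 0.20 ± 0.16 for H3K4me3 (exact permutation p = 0.25 and 0.5, where 0.25 is the smallest that 8 labelings can give). In these lists and the first H3K27ac set the peak names have another style in KO than in WT, and whether both were called with the same settings is not given in the sources used here. SSC had 75277 peaks in WT and 115704 in KO (ratio of covered length 1.93), pBCSP 120792 and 137117 (1.22), and BCSP 113313 and 148530 (1.54). H3K4me3 peaks numbered 33510 and 42399 in SSC (1.35), 28612 and 25468 in pBCSP (0.926) and 32132 and 38500 in BCSP (1.21). Most WT peaks had a KO peak at the same place: 92.8%, 87.3% and 90.5% of H3K4me1 peaks and 92.7%, 81.4% and 91.7% of H3K4me3 peaks in SSC, pBCSP and BCSP. In the other direction 55.0%, 74.0% and 64.3% of KO H3K4me1 peaks and 71.1%, 91.5% and 76.0% of KO H3K4me3 peaks overlapped a WT peak. The stricter threshold left 5 H3K4me1 peaks in WT SSC against 5871 in KO, and 4592 to 14112 in the pBCSP and BCSP lists. The SSC ratios for this mark thus rest on 1 weak WT list.

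At the Paxip1 promoter H3K4me3 peaks were called in all 6 libraries. The authors' fold was 13.8, 15.6 and 17.3 in WT SSC, pBCSP and BCSP and 8.60, 7.23 and 11.8 in KO. Folds also depend on the enrichment of each library, so those given here were not tested between genotypes. The median H3K4me3 fold over all peaks was 5.83, 8.31 and 7.44 in WT and 5.19, 8.67 and 6.69 in KO, in the same order. An H3K27ac peak lay there in the first set in each WT population, at 27791419 to 27792591 on chromosome 5 in SSC (fold 53.6), and in KO in SSC alone (fold 9.01); a WT pBCSP peak was the sole second-set peak. Pgk1 (chromosome X, 106187100 to 106203699) had an H3K27ac peak in the first set in KO SSC (106186718 to 106187840, fold 12.1) and KO BCSP (106186125 to 106186495, fold 3.78) and in no WT list. Of 19 glycolysis promoters, 0 to 4 held an H3K27ac peak in any library and all 19 held H3K4me3 in every library. Promoter ends were chosen by H3K4me3 in these same libraries, so its presence at these promoters and at Paxip1 is largely set by that choice. No H3K27ac peak was called at the promoters of Matn1 (chromosome 4, 130944385 to 130955476) or Col2a1 (chromosome 15, 97975602 to 98004724). The H3K27ac lists hold 137 to 8572 peaks, against 25468 to 42399 for H3K4me3, and Col2a1 had a mean of 34200 CPM in WT. A missing peak in lists this short does not show that H3K27ac was absent, here or at the other genes named. Sox9 (chromosome 11, 112782210 to 112787757) had an H3K27ac peak in the first set in WT pBCSP (fold 4.57) and in the second set in KO BCSP (7.17). Over 14640 genes with a promoter end, H3K4me1 lay at 66.9% of promoters in WT SSC and 92.0% in KO SSC, and at 89.3% to 94.7% in the other populations. The WT SSC list was the weakest for this mark, with a highest -log10 q of 6.9 against 10.02 to 12.29 in the others. Its low share may come from this 1 list and cannot be told from a gain in KO.

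Genes whose promoter held a peak in 1 genotype only were compared with their RNA. Of 17 such sets, 0 passed by camera (smallest adjusted p 0.282; 0.952 with an estimated correlation). The smallest was for genes with H3K4me3 in KO SSC only, where 288 measured genes had a median of -0.78 log2 against -0.22 over all genes. With the stricter threshold 3 sets passed: H3K4me3 in KO SSC only (-0.95, adjusted p = 0.009), in WT BCSP only (0.29, 0.0122) and in KO BCSP only (-0.49, 0.0356). Their adjusted p with an estimated correlation was 0.914, 0.35 and 0.914.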

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

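The tests on other groupings of the libraries, on the SSC KO library with few genes read, on summed counts, on abundant chondrocyte genes and on H3K4me3 and nested peak lists were chosen after the results were seen.

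Glycolysis genes were higher in KO (median 1.27 log2 on average, Pgk1 3.10-fold). Without the SSC KO library with few genes read the median was 1.12 ± 0.12, with 19 of 21 genes above 0. Without the 3 WT libraries with Xist reads it was 1.38 ± 0.13, with 20 above 0. These values argue against either as the whole cause. Their errors are over the KO libraries taken as independent, whereas same-numbered KO libraries had correlated deviations across populations (0.29 to 0.49). Handling that differed between genotypes, such as time or oxygen during dissociation, and loss of PTIP in cells of the Col2a1 lineage may each raise glycolysis and hypoxia genes, and they cannot be told apart with 2 replicates per genotype and no label of the day.

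On average 205 genes passed in edgeR. Only the real grouping among 100 of the 108 possible groupings of the libraries within populations gave 205 genes, and the highest of the others gave 0. These groupings treat the libraries as independent, whereas same-numbered libraries of a genotype had correlated deviations across populations (0.28 to 0.49). Taken as 2 units per genotype they allow only 3 groupings, too few for a share under 0.05. With counts summed into these units 0 genes passed in edgeR (1505 at an unadjusted p under 0.05; 44 passed in limma with a shared correlation).

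Chondrocyte genes were higher in KO (median 1.15 log2), led by Matn1, while Col2a1 was not. Without the SSC KO library with few genes read the median was 1.08 ± 0.22 with 24 of 24 above 0 (error over KO libraries, as for glycolysis genes). This argues against that library as the whole cause. Fewer cells of other types in the KO sorts may raise chondrocyte genes, and the endothelial, adipocyte and tendon lists were lower by camera, though not with an estimated correlation (adjusted p = 0.569 each), with none of their genes past the threshold and, for adipocyte genes, mostly in the second KO replicates (-3.41 to -4.55 against -0.64 to -1.29). The 4 chondrocyte genes most abundant in WT (Col2a1, Cnmd, Col9a1 and Chad) had a median of 0.59 ± 0.47 against 1.15 ± 0.20 for the others. Here the errors come from the spread across genes, which are not independent replicates. The gap lies within the sum of the errors, so this comparison cannot separate a change in cell mixture from a change within chondrocyte-like cells. By gene, Cnmd (1.4 ± 0.25 log2) and Col9a1 (1.16 ± 0.21) rose, while Col2a1 (-0.07 ± 0.24) and Chad (0.02 ± 0.4) did not. Loss of cells without chondrocyte transcripts would raise all 4 alike. These values argue against that loss as the whole cause for these 4 genes, with errors that take the libraries as independent. How much a change in mixture adds stays open. Loss of PTIP, which the design names, stays open and was not tested apart from these.

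H3K27ac peak numbers had a mean log2 ratio of KO to WT of 1.65 in SSC, -1.16 in pBCSP and 1.9 in BCSP, a difference in sign between populations that was not tested. Lists that differ only in how many weak peaks passed would be nested, and the longer list of a pair overlapped 26.5% to 51.1% of the shorter one (51.09% at most), but lists of 1 genotype in different sets overlapped no more (23.8% to 46.5%), so this leaves that account open. The H3K4me3 peak numbers moved the same way as those of H3K27ac in 3 of 3 populations, while H3K4me1 in pBCSP moved the other way (ratio 1.14), as did the stricter first-set BCSP lists (0.2 for H3K27ac and 1.22 for H3K4me3). Depth or enrichment of each immunoprecipitation may set these numbers, and so may peak calling that differed between genotypes. These and a change of the marks after loss of PTIP cannot be told apart, as the peak lists carry no read depth.

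SSC KO replicate 2 stood apart from the other 5 KO libraries in genes with a read (13987) and with at least 10 reads (11743). Both values come from the same library and overlap. They are among 12 tests, of 6 measures in each genotype, each of which marks a library about 1 time in 20 by chance.

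The KO effect on several lists differed between populations by camera with the preset correlation, and by neither the directional p of fry nor the estimated correlation; in the mixed test of fry mitochondrially encoded transcripts passed (0.0277 for SSC minus pBCSP and 0.0171 for pBCSP minus BCSP). For SSC minus pBCSP the median difference in log2 was 1.06 for mitochondrially encoded transcripts, 2.63 for leukocyte genes (adjusted p = 0.000192; adjusted p = 0.261 with an estimated correlation for both lists) and 1.27 for endothelial genes (0.0119; 0.83). The leukocyte value leans on members with a group at 0, as the pBCSP median of -3.27 became -1.48 at their bound. Against the WT mean, leukocyte medians in KO replicates 1 and 2 were -0.36 and -1.65 in SSC and -1.41 and -1.76 in pBCSP. For SSC minus BCSP it was -0.84 for chondrocyte genes, 0.54 for progenitor genes (0.00484), -1.25 for G2 and M phase (2.17e-07), 0.28 for interferon (0.0281), 0.95 for leukocyte (0.0163), 1.67 for endothelial (0.0163) and 1.48 for muscle genes (0.00484), each with an adjusted p above 0.9 with an estimated correlation. For pBCSP minus BCSP it was -0.44 for chondrocyte genes (0.000104), -1.28 for osteoblast genes (0.000104), -0.64 for G2 and M phase (0.000138), 1.34 for Notch targets (0.0026; 0.692 with an estimated correlation for these 4) and -1.22 for mitochondrially encoded transcripts. Osteoblast medians against the WT mean were -0.38 in pBCSP and 0.41 in BCSP in the first KO replicates and -1.29 and -1.57 in the second. The second replicates thus did not share the sign of the osteoblast difference.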

How the results depend on the processing

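Fits with 1 library per KO group, of pBCSP and BCSP alone, with quality weights, with summed counts or with a shared correlation, and lists without a library, were tests chosen after the data were seen. No named gene with a call in the reported fits changed direction under the alternatives run. Of those without a call, 3 turned from higher to lower and passed when the KO second replicates stood alone. Flt1, an endothelial receptor gene, went in SSC from 0.99 to -9.13 without SSC KO replicate 1 and -9.17 with the KO first replicates out (2.00 without SSC KO replicate 2). Tek, another, went in SSC from 0.58 to -6.26 with the KO first replicates out. Nfatc1, an osteoclast factor, went from 0.13 to -1.88 in pBCSP with those out. SSC KO replicate 2 had 0 counts of Flt1 and Tek, so these fitted values are no measure of size. Over 24 alternatives to the average effect, Pgk1 kept its call in 14, Ldha in 13 (log2 1.22 to 1.78), Matn1 in 14 (2.41 to 3.38), Paxip1 in 12 (-7.16 to -3.57) and Ppp1r3b in 8 (2.04 to 5.75), with adjusted p up to 0.591 over the named genes. The number of genes that passed depended on the tool, the filter and single libraries. Without the filter on low counts it was 395 in SSC, 260 in pBCSP, 337 in BCSP, 1882 on average, 50 for effects that differ between populations. For the WT comparisons of pBCSP with SSC and BCSP with pBCSP it was 133 and 107. DESeq2 gave 174, 107, 124, 1735, 3, 40 and 36 in that order. With size factors in edgeR the average count was 140, and with a log2 change of at least 1 it was 187. With a library left out the SSC count ran from 0 to 5908, the average from 0 to 6147 and the differing effects from 0 to 2082. The upper ends came without SSC KO replicate 1, and the average was 0 without any WT library and without pBCSP KO replicate 2 or BCSP KO replicate 2. With only the 4 libraries compared the WT comparisons gave 110 and 417. With the KO second replicates out the counts were 14 in pBCSP, 661 on average, and 189 and 316 in the WT comparisons; with the KO first replicates out they were 8818 in SSC, 2819 in pBCSP, 2977 in BCSP, 9529 on average, 4012 for differing effects, and 179 and 320. Fits with 1 library per KO group take their spread largely from WT, which is tighter. Quality weights in limma gave 19 in BCSP, 84 and 257 in the WT comparisons and 292 on average. The average count was 0 with pBCSP and BCSP alone, 0 with summed counts (1505 at an unadjusted p under 0.05 in edgeR), 44 in limma with a shared correlation and 462 without it. The cause of the other moves was not tested.

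The replicate number as a block gave 141 genes on average, 112 of them among the 205. Deviations of same-numbered KO and WT libraries of a population had correlations of 0.01, -0.02 and -0.08, so the numbers do not pair KO with WT. With the block 4 of the 9 lists passed in SSC, and the calls of oxidative phosphorylation (adjusted p = 0.0551), Notch (0.0551), erythroid (0.0748), pericyte (0.0776) and Schwann cell genes (0.0551) were lost, as was that of leukocyte genes between WT BCSP and pBCSP (0.0619).

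Under an estimated correlation 0 lists passed in all 6 comparisons, and with fry 0 in 5 and 2 on average, where camera passed 9 in SSC, 16 in pBCSP, 15 in BCSP, 12 on average, and 12 and 11 in the WT comparisons. In SSC 5 passed without either KO replicate, in pBCSP 6 without KO replicate 2, 17 without pBCSP KO replicate 1 and 10 with the KO second replicates out. With 1 library per KO group, the average calls of G2 and M phase (0.133), BMP and TGF-beta (0.408) and Notch genes (0.153) were lost with the second replicates out and that of erythroid genes (0.11) with the first out.

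The share of WT H3K4me1 peaks overlapped in KO in SSC, pBCSP and BCSP was 88.3%, 80.9% and 85.4% when 50% of the peak had to overlap, 60%, 54.0% and 50.7% at the stricter threshold and 79.0%, 82.9% and 81.6% with equal numbers of peaks. For H3K4me3 it was 90.5%, 77.2% and 89.9%, then 98.5%, 85.2% and 96.6%, then 86.4%, 87.4% and 86.4%. The stricter H3K27ac lists gave mean log2 ratios of 2.01, -0.60 and 0.20 (exact permutation p = 0.333, 0.667 and 1). Promoter sets at the stricter threshold had medians of -0.95 for H3K4me3 in KO SSC only, 0.29 in WT BCSP only and -0.49 in KO BCSP only.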

Other observations

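Genes in this part were chosen after their values were seen, and the tests on the glucocorticoid and collagen lists were chosen after the results on single genes were seen.

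Single genes that rose on average in KO include Serpinh1, a collagen chaperone (0.98 log2, adjusted p = 0.0495), P3h4 (0.93), Pdia4, a disulfide isomerase (1.58, 0.0266), Creld2 (1.19) and Rcn1 (1.33). Ndufa4l2 (2.36 ± 0.29, 0.0244), Cox4i2 (2.07, 0.0244) and Fam162a (2.65, 0.0266), which encode mitochondrial proteins, rose too, while the oxidative phosphorylation list did not pass (adjusted p = 0.0583). For 16 other collagen folding and secretion genes the median was 0.26 log2, with 12 of 16 above 0 and 0 past the threshold (camera p = 0.00157, and 0.145 with an estimated correlation). Whether the collagen folding machinery is higher in KO stays open.

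Besides Fkbp5, single genes that glucocorticoids induce and that fell on average in KO include Pdk4, a kinase that inhibits pyruvate dehydrogenase (-1.39 log2, adjusted p = 0.049), Glul, which makes glutamine (-1.50, 0.0443), and Mt1, a metallothionein (-1.15, 0.0474). The lipase gene Pnpla2 (-1.51 ± 0.27, 0.0461), Prg4, which encodes lubricin of joint surfaces (-1.10 ± 0.14, 0.0266), and the cytokine receptor gene Lifr (-1.49, 0.0472) fell as well. For 14 other glucocorticoid-induced genes the median was -1.07 log2, with 13 of 14 below 0 and 0 past the threshold (camera p = 0.00023, and 0.141 with an estimated correlation). A lower glucocorticoid response in KO may account for this, in the animals or during handling of the cells, and these data leave it open.

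Xist, the RNA of the inactive X chromosome, had 9.34, 12.9 and 15.2 CPM in the first WT replicate of the 3 populations. It had at most 1.83 CPM in the other libraries, while the Y-linked Ddx3y had 74.7 to 209 CPM in all 12. CPM of Xist and Ddx3y use total counts without TMM scaling. The second WT replicates had 0 CPM of Xist and more Ddx3y than the first (148 to 209 against 74.7 to 85.8 CPM). These values argue against the 2 WT replicates of a population coming from the same animals. For the KO replicates this stays open. Mitochondrially encoded transcripts took 0.266% and 0.325% of counts in the pBCSP KO libraries and 0.437% to 0.639% in the others. The H3K27ac peak at the Paxip1 promoter in WT SSC had the highest fold (53.6) and -log10 q (178) of the 1828 peaks in its list.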
